A study of Mus musculus with 15 samples.

How the data were processed

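Total RNA from mouse brain was labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. The labels describe 15 samples: 3 wild-type (WT) mice and 3 APP/PS1 mice at each of 1, 3, 6 and 9 months of age. APP/PS1 mice are a transgenic model of Alzheimer's disease. Every title carries the same replicate number, so replicates were numbered in accession order, and these numbers pair no samples. Per the series' design text each age had its own WT controls, but the sample labels give no age for the WT mice, so age and genotype could not be separated in any comparison against WT. The labels name 1 male and 2 females per group while the design text names males.

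Scanner files of 14 arrays were used. Their deposited spot intensities were made with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. The intensity used is the processed signal, for which the file headers record background subtraction and spatial detrending within an array. Its 75th percentile differed between arrays, so it was scaled as described below. The files also hold other deposited values: flags of 0 or 1 for each spot (well above background, non-uniform, population outlier). A deposited value table of the series was tested against the scanner files. In each of the 14 columns with a scanner file, all 62513 rows equalled the mean local background intensity around the spot within 0.001. The column medians of all 15 samples lay between 27.9 and 36.8 intensity units. The table therefore held no expression values, its scale is linear intensity of background, and its direction as a measure of expression does not apply. The third WT sample has a column there, with 56000 rows, and no scanner file was used for it, so it entered no comparison.

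The 3 pairs of arrays made of replicates 2 and 3 at 1, 3 and 6 months differed by less than the error the scanner software gives. The median absolute log2 difference was 0.149 to 0.241 times the combined error, against 0.468 to 0.837 in the other 10 pairs within a group. Over the printed copies of the 20 negative probes, the residuals of the 2 arrays correlated at 0.749 to 0.914, against at most 0.334 in the 88 other pairs. Arrays of one group with such a correlation above 0.5 were averaged and counted as 1 sample. This left 11 samples: 2 WT, 2 at each of 1, 3 and 6 months, and 3 at 9 months. The plan fixed before the data were examined had the 14 arrays as separate samples. The averaging was decided after the data, including the counts from all 14 arrays, had been seen, so the 14-array counts are given beside the main ones. The 14-array counts treat the near-identical arrays of a pair as independent, so their p-values may be too small.

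The 8 arrays of WT replicates 1 and 2 and of replicates 1 and 2 at 1, 3 and 6 months were scanned at 356 V and lay at 8 distinct positions, as on one slide. Replicate 3 at 1, 3 and 6 months was scanned at 355 V, and all 3 arrays at 9 months at 354 V. Slide identifiers and dates were not used here. Because the 9-month arrays shared no scan setting with another group, batch and group cannot be told apart for 9 months. Comparisons among WT, 1, 3 and 6 months rest on the first set, with the 355 V array of each pair averaged into replicate 2. Whether those arrays are repeated scans is not given in the labels. Within the 356 V set the arrays of each of these groups lay side by side. Position and group can therefore not be told apart there either. The fit without the 9-month arrays gives the values for these groups alone.

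Control spots and the 1200 spots of the 20 negative probes were left out. The log2 of the processed signal was taken and the 75th percentile of each array subtracted. Spots of one probe were averaged without spots flagged as outliers, and 134 single-spot probes with a non-uniform spot on any array were left out. Probes well above background on 3 or more arrays were kept (48298 probes). WT had 2 arrays, so a probe well above background in WT alone could not be kept. A probe well above background at a single APP/PS1 age could be, so the filter did not treat the 2 directions alike. For genes with several probes the brightest was used, which gave 48294 features. Between 68.1% and 82.4% of the 59994 spots were well above background on an array, and the number of arrays limits the precision. Over the 15 reference genes printed 20 times each, the spread of log2 values between copies on one array was 0.0931 to 0.162.

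The arrays name probes mainly by internal codes. Of 59709 distinct probes, 116 had a RefSeq identifier that matched a gene symbol in the reference table of mouse genes (assembly GRCm38.p6, used for names alone), giving 112 symbols, of which 85 were kept. The other 59593 probes are given by their code. Probes of gene families with similar copies, such as the Ccl21, Amy2, Fam205a, Ssty, Btbd35f, Vmn1r and histone H2A genes, can read more than one copy. No coordinates are given because the build of the array design is not given in the sources used here. Of 857 genes in 44 lists fixed before the data were examined (pathways, cell type markers and others), 4 were named and kept (B2m, Hsp90ab1, Hmgcs1 and Rpl13a), at most 1 in a list. No list could be tested. Probes were instead sorted, after their names were seen, into 8 classes by the form of the name.

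Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 11 samples, 6 residual degrees of freedom). A feature was called at a Benjamini-Hochberg adjusted p below 0.05. The labels do not say how samples were pooled or which animals were related, so the p-values measure the spread between these samples, which may be technical. Comparisons were each age against WT, the mean of the 4 ages against WT, 9 against 1 months, an F test across ages, labelled females against labelled males with group as a covariate, and, added after the scan settings were seen, 6 against 1 months. Class shifts were tested with camera (preset correlation 0.01), with an estimated correlation and fry beside it.

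Named features were fixed by rule before the data were examined. App and Prnp, and for the labelled sexes Xist, Ddx3y, Uty, Kdm5d and Eif2s3y, were to be given always, but no probe carried those names and they were not analysed here. A further item of the rule is not reported here. Among called features whose samples in the 2 groups did not overlap, the 6 largest increases and 6 largest decreases with an approved-type symbol were taken, then the 2 largest of each kind among all other features. For a described gene list, up to 4 members were to be named. For the F test, size was the range of the 4 group means. Where a probe was well above background on no array of a group, the fold is a bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

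The fit was tested on simulated data for 48294 features, of which 50 were changed at each of 4 fold sizes. At 9 months against WT, 86% of the features changed 4-fold, 50% of those changed 2-fold and 10% of those changed 1.5-fold were recovered. At 1 month against WT the shares were 82%, 44% and 10%. Of 130 calls at 9 months 11 were false, and of 123 calls at 1 month 10 were. Noise was drawn independently for each feature with the fitted variances and no batch effect. Far fewer features were changed than were called in the real data, so these shares may not hold there. Alternatives fixed beforehand were quantile normalization, other filters on dim probes, other rules for probes of one gene, a trended robust prior, array weights, only the groups compared, labelled sex as a covariate, and leaving out each sample. The fit of all 14 arrays as samples was the plan as first fixed, and is kept as an alternative. Added after the data were seen were normexp and the first array of each pair. Normexp used the median spot and background intensities (offset 50), since the planned mean spot signal is not a column used here. Also added were a fit without the 9-month arrays and one of separate arrays with scan setting as a block, again without the 9-month arrays. For the overlap of ages, a separate WT sample for each of 2 ages was added too.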

Results

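The arrays measured brain RNA of WT mice and of APP/PS1 mice at 4 ages, with probes for mRNAs and long noncoding RNAs. After 3 pairs of near-identical arrays were each counted as 1 sample, there were 2 WT samples, 2 samples at each of 1, 3 and 6 months, and 3 samples at 9 months. The 75th percentile of spot intensity ran from 384 to 566 over the 14 arrays. The first principal component held 30.1% of the variance and placed the 3 samples at 9 months between 88.6 and 93.2, while the other 8 samples lay between -50.3 and 1.37. The 9-month arrays were also scanned apart from all others, so slide or scan and age cannot be told apart there.

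**Figure D1:**
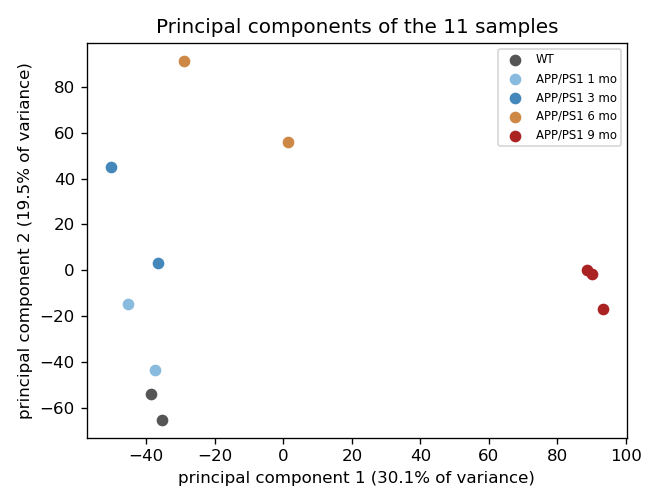
Principal component 1 (horizontal, 30.1% of variance) against component 2 (vertical, 19.5% of variance) for the 11 samples, 1 point per sample, coloured by group. The 3 samples at 9 months sit alone on the right, between 88.6 and 93.2 on component 1.

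Whether the brain transcriptome of young APP/PS1 mice differed from WT was addressed at 1 month. B2m, the light chain of MHC class I, fell by 0.69 (SE 0.07) on the log2 scale, from a mean of 6.44 ± 0.0055 (SD, n = 2) to 5.76 ± 0.03 (SD, n = 2). B2m is one of the 15 reference gene probes, whose median log2 change was -0.16. Ccl28, a mucosal chemokine, fell by 1.34 (SE 0.18), Ccdc82 by 0.83 (SE 0.13), Amy2a5, a pancreatic amylase gene, by 0.64 (SE 0.11), Fam177a2 by 0.63 (SE 0.08) and Fam205a2 by 0.56 (SE 0.12). Mia3, which acts in export of collagen from the endoplasmic reticulum, rose by 0.60 (SE 0.14). The limma adjusted p was 0.0021 for B2m, 0.0059 for Ccl28 and 0.044 for Mia3. With normexp Mia3 turned to -0.050, and its call was lost in 12 of 26 alternatives, that of Fam205a2 in 7 and those of Amy2a5 and Ccdc82 in 4 each. With the WT and 1-month samples alone, all 7 named symbols lost their call (limma adjusted p from 0.0936 to 0.158). Probe ASMM9PARTA004055 and probe BC040767_P1 were well above background on no WT array and were at least 15.6-fold and 16.9-fold higher at 1 month. Over 25 alternatives their log2 changes were as small as 1.73 and 1.87, below these bounds. Probes ASMM9PARTA030909 and ASMM9PARTA003926 were well above background on no array at 1 month and were at least 49.1-fold and 13.7-fold lower. The former was not called with the WT and 1-month samples alone (limma adjusted p = 0.0838). Across the same alternatives the log2 changes of these 2 were as small as -3.59 and -2.26. Of 48294 features, 2130 were higher and 1999 lower. In this and the other comparisons against WT, the filter could not keep probes well above background in WT alone. The split of higher and lower features is therefore not even-handed. Among the 62 genes with an approved-type symbol, 1 was higher and 7 were lower. With normexp 969 were higher and 2942 lower. The count of 4129 was 10644 with the 14 arrays as separate samples. Without the 9-month arrays it was 7610 with scan setting as a block over the separate arrays, and 1888 over the averaged samples. With the WT and 1-month samples alone it was 114. Leaving out 1 sample gave 1393 (without replicate 1 at 1 month), 1520 (without replicate 2 at 1 month), 1915 (without WT replicate 1) and 2463 (without WT replicate 2).

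At 3 months, Ccl28 fell by 1.57 (SE 0.18) on the log2 scale and Fam205a2 by 1.11 (SE 0.12) against WT. The change of Ccl28 was as small as -0.73 over its 25 alternatives. Amy2a5 fell by 0.66 (SE 0.11), Nono, a paraspeckle protein gene, by 0.44 (SE 0.11), and Gk, glycerol kinase, by 0.30 (SE 0.07). H2ac19, a histone H2A gene, rose by 0.55 (SE 0.11), Tagap, a GTPase-activating protein gene of T cells, by 0.51 (SE 0.11) and Jrkl by 0.40 (SE 0.10). B2m, which was lower at 1 month, lay at 6.44 ± 0.03 (SD, n = 2) and did not pass the limma test (log2 difference 0.00022, adjusted p = 0.999). Probe ASMM9PARTA024808 was at least 28.3-fold and ASMM9PARTA014677 at least 33.2-fold higher than in WT, where neither was well above background. The latter was not called with the 2 groups alone (limma adjusted p = 0.0674). Over 25 alternatives the log2 changes of these 2 were as small as 2.56 and 3.14, below the bounds. ASMM9PARTA021726 fell by 6.10 (SE 0.11) on the log2 scale, and ASMM9PARTA003926 was also lower and well above background on no array at 3 months. In all, 3112 features were higher and 1797 lower by limma. Among the 62 genes with an approved-type symbol, 3 were higher and 5 lower. The count of 4909 was 10428 with 14 arrays and 7835 with scan setting as a block over these without the 9-month arrays. It was 2241 with normexp, 2558 over the averaged samples without the 9-month arrays and 166 with the 2 groups alone. With the 2 groups alone all 8 named symbols lost their call (limma adjusted p from 0.0682 to 0.220). Over the 26 alternatives the calls of Nono, Gk and Jrkl were each lost in 13 to 15, that of Tagap in 6, of H2ac19 in 5, of Amy2a5 in 3, and of Ccl28 (25 alternatives) and Fam205a2 in 1. Without 1 sample it was 2149 (replicate 1 at 3 months), 2703 (WT replicate 1) and 2928 (WT replicate 2).

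At 6 months Ccl28 fell by 1.96 (SE 0.18) and Fam205a2 by 1.41 (SE 0.12) on the log2 scale. The change of Ccl28 was as small as -1.13 over its 25 alternatives. B2m fell by 0.70 (SE 0.07), Actb, cytoskeletal actin, by 0.59 (SE 0.11), Nono by 0.56 (SE 0.11) and Fam177a2 by 0.51 (SE 0.08). B2m, Actb and Nono are among the 15 reference gene probes, of which 0 were higher and 4 lower (class median -0.11). Amy2a5, lower than WT at 1 and 3 months, rose by 1.04 (SE 0.11). Ssty2, a Y-linked gene of spermatids, rose by 1.86 (SE 0.31), Mia3 by 0.65 (SE 0.14), Tagap by 0.52 (SE 0.11) and Jrkl by 0.43 (SE 0.10). Ssty2 was well above background on no WT array and on 2 of the 3 arrays at 6 months, which gives no fold above 1, and it turned to -0.52 with normexp. Probe ASMM9PARTA024808 was at least 28.0-fold and ASMM9PARTA030969 at least 18.7-fold higher. The latter lay at -2.69 and 2.10 in the 2 samples, and its call was lost in 4 of 25 alternatives (normexp, the 2 groups alone and without either WT replicate). Probes ASMM9PARTA030909 and ASMM9PARTA039168 were at least 62.9-fold and 39.8-fold lower. Over 25 alternatives the log2 changes of these 2 were as small as -3.75 and -3.07, below the bounds. Those of ASMM9PARTA024808 and ASMM9PARTA030969 were as small as 2.57 and 2.39, also below their bounds. By limma 6059 features were higher and 4078 lower, and 5 of the 62 symbols were higher and 8 lower. With normexp 3493 were higher and 8912 lower. The count of 10137 was 16846 with 14 arrays, 1506 with the 2 groups alone and 6611 without WT replicate 1. With the 2 groups alone 7 of the 11 named symbols lost their call, and Ssty2, Amy2a5, Ccl28 and Fam205a2 passed. The calls of Mia3, Tagap and Jrkl were lost in 4 of 26 alternatives each, and Mia3 was 0.013 with normexp (limma adjusted p = 0.946). The share of spots well above background reached 82.4% at 6 months against at most 69.2% in WT.

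The largest named increases of the study were at 9 months. Ccl21b and Ccl21c, chemokine genes that guide cells through CCR7, rose by 4.46 (SE 0.17) and 3.90 (SE 0.13) on the log2 scale against WT, and Ccl28 rose by 3.20 (SE 0.17). B2m, lower than WT at 1 and 6 months, rose by 0.54 (SE 0.07), and is named after its value was seen. The 2 Ccl21 genes are near-identical copies, so their probes may read the same transcripts and are not independent. Ssty2 rose by 2.30 (SE 0.28), at least 1.04-fold, Nim1k, a kinase gene, by 1.88 (SE 0.44), and Btbd35f4 by 1.29 (SE 0.25), at least 1.62-fold. Spry3, an inhibitor of growth factor signalling, fell by 0.73 (SE 0.09), the pheromone receptor gene Vmn1r241 by 0.61 (SE 0.11), Nono by 0.60 (SE 0.10), Vmn1r257 by 0.44 (SE 0.13), H2al2b by 0.35 (SE 0.09) and Hsp90ab1, a chaperone, by 0.33 (SE 0.08). With normexp Ssty2 turned to -0.30 and Btbd35f4 to -0.17, while Nim1k was 0.54. The call of Vmn1r257 was lost in 8 of 24 alternatives, those of H2al2b and Hsp90ab1 in 4 of 24 each, that of Nim1k in 2 of 23 (without either WT replicate) and that of Fam205a2, higher by 0.50, in 1 of 24. Probes ASMM9PARTA039476 and ASMM9PARTA050454 were at least 292-fold and 122-fold higher, and ASMM9PARTA030909 was at least 50.2-fold lower. Over 23 alternatives their log2 changes were as small as 5.73, 4.72 and -3.56, below these bounds. ASMM9PARTA029273 fell by 6.15 (SE 0.10) on the log2 scale. By limma 8407 features were higher and 6510 lower (7219 and 7782 with quantile normalization), and 14 of the 62 symbols were higher and 7 lower. With normexp 5593 were higher and 11982 lower. The count of 14917 was 9905 without WT replicate 1, and slide or scan cannot be separated from this group.

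**Figure D2:**
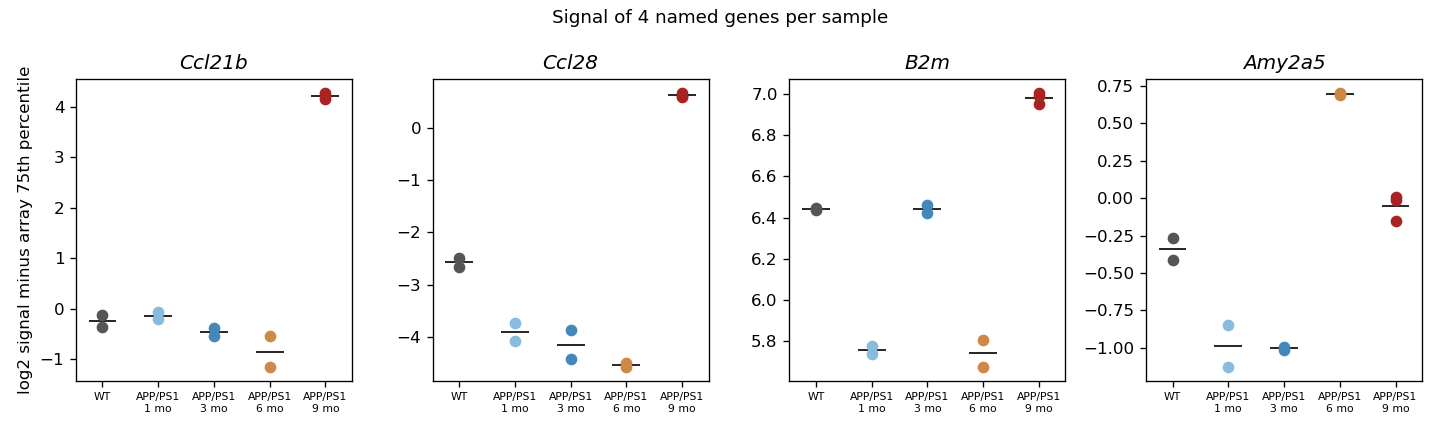
Log2 signal minus the array's 75th percentile (vertical) for Ccl21b, Ccl28, B2m and Amy2a5 in each group (horizontal), 1 point per sample, with the group mean as a line. Ccl21b averaged 4.22 at 9 months against -0.25 in WT, and Ccl28 fell to -4.53 at 6 months before standing at 0.62 at 9 months.

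For the mean of the 4 ages against WT, Nono fell by 0.45 (SE 0.08) and Actb fell by 0.35 (SE 0.08) on the log2 scale. Mia3 rose by 0.58 (SE 0.11), and turned to -0.013 with normexp. Ssty2 was called higher but was well above background on no array of WT, 1 or 3 months, so no fold is given, and its log2 value turned to -0.46 with normexp. The call of Actb was lost in 8 of 23 alternatives, and those of Nono, Mia3 and Ssty2 were lost without either WT replicate. Probe ASMM9PARTA024808 was at least 27.2-fold and ASMM9PARTA018523 at least 6.43-fold higher. Over 22 alternatives their log2 changes were as small as 2.47 and 0.98, below these bounds. ASMM9PARTA030909 and ASMM9PARTA051561 were lower. No fold is given for these 2, since the former was well above background on no array at 1, 6 and 9 months and the latter on none at 6 and 9 months. By limma 4558 features were higher and 2925 lower, and 3849 of them had samples that did not overlap. Over all features the samples of 11.8% did not overlap, where chance gives 3.64% if all samples are exchangeable. Samples of one group are not, so no excess particular to WT can be read from these shares. The count of 7483 was 12562 with 14 arrays, 14804 with normexp (3016 higher and 11788 lower), 2909 without WT replicate 1 and 3236 without WT replicate 2.

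How the transgenic brain changed with age was addressed by setting ages against each other, in the fit that also held the WT samples. Slide or scan cannot be told apart from the 9-month group, so 9 against 1 months and the F test do not isolate age. Between 1 and 9 months, Ccl28 rose by 4.53 (SE 0.17) on the log2 scale, Ccl21b by 4.35 (SE 0.17), Ccl21c by 3.89 (SE 0.13), Nim1k by 2.16 (SE 0.44), Btbd35f4 by 1.39 (SE 0.25) and Ssty2 by 1.38 (SE 0.28), the last at least 1.31-fold. Vmn1r241 fell by 0.55 (SE 0.11), Spry3 by 0.43 (SE 0.09), H2al2b by 0.42 (SE 0.09), Nono by 0.42 (SE 0.10) and Hsp90ab1 by 0.31 (SE 0.08). Probes ASMM9PARTA031158 and ASMM9PARTA050454 were at least 321-fold and 153-fold higher. Over 23 alternatives their log2 changes were as small as 6.34 and 5.33, below these bounds. ASMM9PARTA029273 fell by 5.59 (SE 0.10). ASMM9PARTA015481 was lower too, by 5.52 (SE 0.20), but was well above background on 1 of 3 arrays at 9 months, and its value was -2.81 with normexp. Btbd35f4 was well above background on 1 of 3 arrays at 1 month. With normexp Ssty2 was 0.30 (limma adjusted p = 0.389) and Btbd35f4 0.49 (adjusted p = 0.139), and both calls were lost, that of Ssty2 also without replicate 2 at 1 month. The call of Hsp90ab1 was lost in 4 of 24 alternatives, those of Nono, H2al2b and Vmn1r241 in 2 each, that of Spry3 in 1 and that of Nim1k in 1 of 23. By limma 8586 features were higher and 7250 lower at 9 months (7371 and 8556 with quantile normalization, 6185 and 4426 with normexp). Of the 62 symbols 17 were higher and 5 lower. The count of 15836 was 9766 without replicate 2 at 1 month. Across the 4 ages 20341 features passed the F test, 13342 with normexp and 19567 with the WT samples left out. Its widest ranges of group means among symbols were 5.15 for Ccl28, 5.06 for Ccl21b, 4.18 for Ccl21c, 2.31 for Nim1k, 1.91 for Fam205a2 and 1.70 for Amy2a5. Among other features they were 10.4 for ASMM9PARTA031158 and 9.59 for ASMM9PARTA050454, ranges that include groups not well above background.

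Ages 1 and 6 months share the scan set of 356 V, and their comparison was added after the scan settings were seen. Each age lay at its own positions in that set, so position and age cannot be told apart here. Amy2a5 rose by 1.68 (SE 0.11), Ccdc82 by 1.03 (SE 0.13), Tagap by 0.64 (SE 0.11), Vamp7, a vesicle fusion protein gene, by 0.58 (SE 0.11), Jrkl by 0.53 (SE 0.10) and Brox by 0.48 (SE 0.12). Fam205a2 fell by 0.85 (SE 0.12), Ccl21b by 0.72 (SE 0.19), Ccl28 by 0.62 (SE 0.18), Nono by 0.38 (SE 0.11), Dhrsx by 0.37 (SE 0.09) and Tsnax by 0.34 (SE 0.09). Probe ASMM9PARTA027745 was at least 89.7-fold higher at 6 months and ASMM9PARTA033120 rose by 7.70 (SE 0.09), while BC040767_P1 and ASMM9PARTA044960 were at least 27.3-fold and 27.2-fold lower. Over 25 alternatives the log2 change was as small as 4.53 for ASMM9PARTA027745, -2.78 for BC040767_P1 and -2.73 for ASMM9PARTA044960, below these bounds. By limma 6227 features were higher and 4485 lower, and 10 of the 62 symbols were higher and 6 lower. The count of 10712 was 18106 with 14 arrays, 16896 with scan setting as a block over these, 6767 with normexp, 2709 with the 2 groups alone, 6417 without replicate 2 at 1 month and 6786 without replicate 1. With the 2 groups alone 10 of the 12 named symbols lost their call, and Amy2a5 and Ccdc82 passed. Calls of Ccl28 and Nono were lost in 15 of 25 and 14 of 26 alternatives, those of Ccl21b and Tsnax in 8 of 26 each, that of Brox in 6, of Dhrsx in 4 and of Jrkl in 2.

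**Figure D3:**
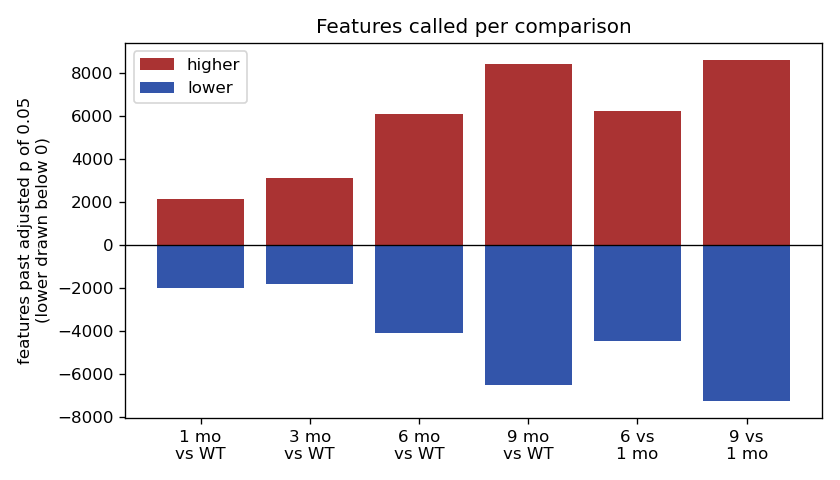
Number of features past a limma adjusted p of 0.05 (vertical), higher drawn above 0 and lower drawn below, for the comparisons of 1, 3, 6 and 9 months with WT and of 6 and 9 months with 1 month (horizontal). The highest bars are at 9 against 1 months, with 8586 higher and 7250 lower.

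Some features were called in the same direction at several ages against the same 2 WT samples. At 1, 3 and 6 months together 654 were higher and 273 lower. Simulated unchanged groups against the shared WT samples gave 0.01 such features on average over 100 draws, and independent lists would give 17.2 and 6.28. The former leaves out all effects, so that hardly a feature is called, and the latter leaves out the shared controls, so neither number measures shared effects. At all 4 ages 548 were higher and 107 lower. At 1 and 6 months 1564 were called in the same direction and 862 in opposite directions. Across features, which are not independent replicates, the covariance of log2 fold changes was 0.145 at 1 and 3 months, 0.154 at 1 and 6, 0.215 at 3 and 6 and 0.218 at 6 and 9 months, against 0.0516 to 0.0519 in simulation. The correlation was 0.509, 0.457, 0.614 and 0.506 for these pairs, against 0.499, 0.499, 0.50 and 0.548 in simulation. With a separate WT sample for each age, an alternative added after the data were seen, the covariance was at least 0.0908, 0.0984, 0.160 and 0.158. Calls recounted that way, with the 2 WT samples assigned in either order, were in the same direction for 546 and 565 features at 1 and 3 months (92 and 112 opposite) and 628 and 705 at 1 and 6 (389 and 432 opposite). They were so for 1340 and 1362 at 3 and 6 (154 and 148 opposite) and 2752 and 2798 at 6 and 9 months (373 and 406 opposite). The fits still shared their other 9 samples, so calls at 2 ages were not independent. With 2 WT samples the overlap of 3 ages cannot be recounted, and part of its 927 features may come from the shared controls. The count of 927 was 2415 with 14 arrays and 1692 with scan setting as a block over these without the 9-month arrays. It was 525 with normexp (172 higher and 353 lower), 484 over the averaged samples without the 9-month arrays and 13 with only the groups compared. It was 403 and 450 without replicate 1 or 2 at 1 month, 548 without replicate 1 at 3 months and 571 without WT replicate 1.

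Probe classes defined by name, after the names were seen, were tested as sets. Of 399 mouse lincRNA probes, 7 were higher and 41 lower at 9 than at 1 month (camera adjusted p = 0.114), and of 2590 lincRNA exon probes 250 were higher and 409 lower (adjusted p = 0.352). Of 246 added transcript probes, which hold most named genes, 74 were higher and 25 lower (adjusted p = 0.0961). With fry, which sets a class against no other probes, the adjusted p was 0.363, 0.298 and 0.000442 for these 3 classes, and 0.00659 for the 43081 unnamed transcript probes. The 15 reference gene probes, with a median log2 change of -0.16 at 1 month against WT, passed camera's test (adjusted p = 0.0131), and did so for the mean of the ages (median -0.11, adjusted p = 0.0209). Both calls were lost with an estimated correlation (camera adjusted p = 0.985) and with quantile normalization (camera adjusted p = 0.434 and 0.140). With fry the adjusted p was 0.0439 and 0.0768. This class holds B2m, Nono, Actb, Gk and Hsp90ab1, whose changes against WT were not adjusted for its shift.

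Between labelled females and labelled males no feature passed limma's adjusted threshold, and 3887 of 48294 had an unadjusted p below 0.05. With the 14 arrays as separate samples 278 passed. That fit counts the arrays of each near-identical pair as independent, and both arrays of each pair are labelled female. Leaving out either WT replicate gives the same sex comparison, since a single WT sample carries no contrast of the sexes.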

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

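All tests of the 3 patterns weighed here were chosen after the results were seen. The fit with quantile normalization was itself fixed beforehand, and its use to weigh a pattern came after.

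B2m, Ccl28, Fam177a2, Fam205a2 and Amy2a5 were called in opposite directions at 2 ages against the same WT samples, and the difference between the ages was itself called by limma. Opposite calls against the same WT samples make that difference larger than either change, so its call adds no further support. For all but Amy2a5 it rests on the 9-month arrays, where slide or scan cannot be told apart from the group. B2m was 1.23 higher on the log2 scale (SE 0.07, adjusted p = 2.09e-05) at 9 than at 1 month, Ccl28 4.53 (SE 0.17, adjusted p = 3.28e-06), Fam177a2 1.06 (SE 0.07, adjusted p = 6.48e-05) and Fam205a2 1.06 (SE 0.11, adjusted p = 0.000323). Amy2a5 was 1.68 higher (SE 0.11, adjusted p = 5.71e-05) at 6 than at 1 month. With the WT and 1-month samples alone all 5 lost their 1-month call (limma adjusted p from 0.0936 to 0.158). Over 26 alternatives Fam205a2 lost it in 7 and Amy2a5 in 4, and the 9-month call of Fam205a2 was lost without WT replicate 1 (adjusted p = 0.0708). Over all features, 829 had opposite calls at 1 and 9 months with the difference called, of which 599 were higher at 9 months.

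Negative probes, which should bind no mouse RNA, were well above background at 7 to 8.75% of their spots in WT. The arrays ranged from 15.9 to 19.5% at 1 month, 6 to 14.3% at 3 months, 21.4 to 35.8% at 6 months and 13 to 27.6% at 9 months.

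Replicates 2 and 3 at 1, 3 and 6 months were nearly identical. Residuals over copies of the negative probes correlated at 0.749 or more in these pairs and at most at 0.334 in others. The pairs shared 20 of the 23 non-uniform spots they could have shared, while no other pair of arrays shared any. This argues against separate arrays of very similar animals. A repeated scan of one array may be the source. The titles give each array of a pair its own code, which a repeated scan does not explain, so this stays open.

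The 9-month samples stood apart from the other 8. Quantile normalization still called 15927 features at 9 against 1 months, which argues against the scaling of each array as the source of that number. The split did depend on scaling, from 8586 higher and 7250 lower to 7371 and 8556. With normexp 10611 were called. Array effects particular to single probes were not tested. Over the 15836 features called, the 6 minus 3 months difference, turned to the sign of the change, had a median of 0.10 to 0.13 in the 4 pairs of samples, a direction that age would give. Arrays at 6 months also had more spots well above background than arrays at 3 months, so this test does not separate age from array brightness. Slide or scan cannot be told apart from the group, since 0 arrays of other groups shared the scan setting.

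Some probes were on in some groups and off in others. Over the 6 pairs of groups scanned together, 51.4% of the probes over 8-fold apart in replicate 1 were over 4-fold apart the same way in replicate 2 (33.3 to 77.0% by pair), which argues against defects of single spots as the whole source. A median of 197 probes (159 to 284 by pair) were over 8-fold apart between groups scanned together, against at most 158 between samples of one group. The median lay above that maximum, but the lowest pair of groups barely did. This margin is too narrow to decide on slide or scan, which stays open. Age and genotype stay open and untested for these probes, as do genetic differences between the mice outside the transgenes.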

How the results depend on the processing

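The 14 arrays as separate samples were the plan as first fixed. The averaging to 11 samples, normexp on the median signals, the first array of each pair, the fit without 9-month arrays and the scan setting block were chosen after the data were seen, and the swaps of sex labels before their result. The causes were not tested. Signal over background limits dim probes, and normexp moved the median log2 change against WT by -0.19 to -0.32. Quantile normalization kept every count within 1.5 times, with 7219 higher and 7782 lower at 9 months and 7371 and 8556 at 9 against 1 months.

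With only the groups compared, the counts were 114, 166 and 1506 at 1, 3 and 6 months against WT, 2709 at 6 against 1 months and 13 for the overlap of 1, 3 and 6 months. Normexp gave 2241 at 3 months, 14804 for the mean of ages, 6767 at 6 against 1 months, 13342 for the F test and 525 for the overlap. The 14 arrays as separate samples gave 10644, 10428 and 16846 at 1, 3 and 6 months, 12562 for the mean, 18106 at 6 against 1 months, 278 for labelled sex (247 higher and 31 lower in females) and 2415 for the overlap. Without the 9-month arrays 1888 and 2558 passed at 1 and 3 months and 484 overlapped. With scan setting as a block over the separate arrays, without those at 9 months, the counts were 7610 and 7835 at 1 and 3 months. They were 16896 at 6 against 1 months and 1692 for the overlap.

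Leaving out 1 sample gave 1393 to 4305 at 1 month, 2149 to 5128 at 3 months, 6611 to 9512 at 6 months, 9905 to 15515 at 9 months, 2909 to 8042 for the mean, 9766 to 16379 at 9 against 1 months, 6417 to 10070 at 6 against 1 months, 15555 to 20331 for the F test, 0 to 290 for labelled sex and 403 to 855 for the overlap. Where a group kept 1 sample, it was assumed to vary like the others.

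Of 107 named results, normexp reversed Mia3 at 1 month (-0.050) and for the mean (-0.013), Ssty2 at 6 months (-0.52), 9 months (-0.30) and for the mean (-0.46), and Btbd35f4 at 9 months (-0.17). It turned camera's direction for reference gene probes, whose medians were -0.057 at 1 month and -0.022 for the mean. Leaving out 1 sample lost 138 of 1177 named calls and the other alternatives 79 of 1449.

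The value table alternatives were not run because its columns hold background. A slide block over the 11 samples coincides with the 9-month group, so it was not run, and dates were not used here. No list test was run. No paired analysis was possible because every title carries the same replicate number. Of the 48 ways to place the sex labels within groups, 7, the real one included, gave 3887 or more features at an unadjusted p below 0.05 (3887 for the real one, highest other 5347), so chance could not be excluded.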

Other observations

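The third WT sample had no spot signal here, and its column of background intensities was set against those of the 14 arrays. Its Spearman correlation with WT replicate 2 was 0.934 over 56000 spots, the next highest being 0.668, and 517 of its 560 brightest background spots were among the brightest of WT replicate 2, against at most 46 elsewhere. In the 3 pairs of near-identical arrays 353 to 457 such spots were shared, at correlations of 0.781 to 0.854. These values describe background only. Whether the third WT sample and WT replicate 2 come from one array could not be tested on spot signal.

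Opposite strands of one lincRNA exon region were measured for 989 regions. At 6 months against WT both strands were called in 46, where 30.3 would be called together if independent (Fisher's exact test, two-sided, p = 0.000881), and 38 of the 46 moved the same way, where 15.4 such regions would be expected. At 9 against 1 months the number was 70, where 65.7 would be expected (Fisher's exact test, p = 0.506), and 49 of the 70 moved the same way, where 34.3 would be expected. For human and mouse lincRNA regions at 6 months it was 0, where 1.52 and 0.619 would be expected (Fisher's exact test, p = 0.371 and 1), and at 9 against 1 months it was 3 and 2, where 3.30 and 1.42 would be expected (Fisher's exact test, p = 1 and 0.632). For 155 uc element regions it was 7 at 6 months, where 4.70 would be expected (Fisher's exact test, p = 0.261), and 16 at 9 against 1 months, where 10.03 would be expected (Fisher's exact test, p = 0.0186). For uc elements 7 and 13 such regions moved the same way, where 2.55 and 5.08 would be expected, and for human and mouse lincRNA regions at 9 against 1 months 2 and 1, where 2.24 and 0.991 would be expected. Directions were not tested. These were all 8 tests, with p-values not adjusted for that number. Regions were taken as independent units though all were measured on the same samples, so the p-values do not measure the spread between mice.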
